A study of Salvia officinalis and Salvia officinalis subsp. lavandulifolia and Salvia sclarea with 15 samples.

How the data were processed

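The study hybridised biotin-labelled genomic DNA of 15 Salvia genotypes, cut with the enzymes AluI and HaeIII after CTAB extraction from leaves, per the labels, to slides carrying 285 subtracted fragments and 14 kinds of control. Each array had 1200 spots, with 4 spots per fragment, and was read in 1 colour. Scanner files of 30 arrays were read; that of S. miltiorrhiza replicate 1 held 0 at every spot and was left out. The 29 arrays used came from 21 slides and 11 hybridisation sessions, and were scanned in 2 periods. Sessions, as used below, follow the hybridisation number in the image name of the file header. The second period held both arrays of S. fruticosa, S. przewalskii, S. microphylla and S. lanceolata and replicate 2 of S. mexicana.

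Per the file headers, the authors quantified spots with PerkinElmer ScanArray Express by an adaptive circle method, and the files give the linear intensity of foreground and local background per spot. In each file the deposited background-subtracted median equals foreground median minus background median, so no normalization had been applied to it. The files also give a ratio of foreground median to the SD of the local background, computed by the scanner software per the file headers. The deposited table of 1 signal value per fragment and genotype carries no description of its scale. Setting each column against the scanner values showed that it holds this scanner ratio averaged over the spots of a fragment, with each array scaled to 1 mean and replicates averaged. Rebuilt this way, 14 of the 15 columns had correlations of at least 0.999999 on the log2 scale. The column of S. miltiorrhiza, set against replicate 2 alone, had r = 0.985. The scale is thereby known to be linear, the values are not centred on 0 and larger values mean more hybridisation. The columns' means lay close together, from 37.17 for S. sclarea to 37.34 for S. miltiorrhiza. What stays unknown is how the authors chose this common mean and how the S. miltiorrhiza column was made. The columns' medians were 24.3 for S. officinalis, 27.4 for its grey and 27.9 for its purple variety, 29.8 for S. lavandulifolia, 24.2 for S. sclarea, 28.6 for S. elegans, 22.2 for S. microphylla, 22.9 for S. mexicana, 24.1 for S. fruticosa, 23.3 for S. lyrata, 25.5 for S. runcinata, 25.2 for S. lanceolata, 27.1 for S. przewalskii, 33.6 for S. sinica and 32.0 for S. miltiorrhiza. Its row P17 follows the HPPR control spots (r = 0.999999 over 14 genotypes), and fragment N17, which lies beside a dye spot, has no row. This table served only as an alternative for the grouping by region.

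From the scanner intensities the median foreground was corrected for the median local background with limma's normexp method (offset 50), converted to log2, averaged over the 4 spots of a fragment and centred on the array's median over fragments. Control spots were left out after background correction. No quantile step was used, since species can truly differ in how many fragments they carry. A fragment counted as detected on an array when at least 50% of its spots exceeded local background by 2 background SDs.

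All genotypes entered 1 limma fit (lmFit and eBayes) with a mean per genotype and no block, so that genotypes share an estimate of the spread with 14 residual degrees of freedom. P-values measure only the spread between these arrays. An F test asked for any difference among genotypes, and contrasts compared pairs of genotypes or a species with the mean of the other 12, with S. officinalis as the mean of its 3 genotypes. P-values were adjusted by Benjamini-Hochberg over 285 fragments, with a threshold of 0.05. Regions were compared on 13 species means (Europe 4, America 4, Asia 3, Africa 2), each region against the mean of the other 3. The native regions come from general botanical knowledge. Distance was 1 minus the Pearson correlation over fragments, tested by permuting region labels 100000 times, and clusters were resampled over fragments 1000 times. For each contrast the rule named the 5 fragments with the largest difference in each direction among those past the threshold whose arrays did not overlap, for each species its 5 largest specific fragments, and the 5 largest F and 5 smallest spreads; because the fragments are anonymous, the text gives the first 2 of each. The groups, tests, naming rule and first list of alternative settings were set before the data were examined.

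Spots marked by the scanner software as other than good were to be left out. They turned out to be mostly dim spots (median net signal 4 and 37 for the marked classes, against 333 for the others), so that leaving them out would remove 20.6% of 8265 fragment values and leave 67 fragments with a value on every array. They were therefore kept, and leaving them out is an alternative. This departs from the plan and was decided after the data were seen.

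The tests were tried on 20 simulated sets of 285 fragments with 40 changed fragments each. With the measured array brightness, 2-fold changes between S. officinalis and its purple variety were called in 82.0% of cases and 4-fold changes in 91.8%, and 6.63% of unchanged fragments were called. With the measured brightness 71.0% of unchanged fragments were called between S. officinalis and S. fruticosa, 1.93% between S. miltiorrhiza and S. sinica, and 0% between S. officinalis and S. lavandulifolia, and 39.4 unchanged fragments per set were called specific to S. fruticosa. For 11 further species 0 unchanged fragments were called specific. Outside the region sets, every genotype had the same true level of a fragment except for the changes put in. Species in the data differ more, so these rates need not hold for fragments called specific there. With equal brightness the simulated counts for S. fruticosa were 0. The planned setting was kept as the one reported, and an alternative was added after the data were seen in which the net signals of every array are brought to 1 median of 206 units before background correction; there 10.8%, 0.0526% and 0% of unchanged fragments were called in those 3 comparisons. Asian 4-fold changes were called in 89.3% of cases with 0.429% of unchanged fragments called, and the region test gave p under 0.05 in 20 of 20 sets with an Asian effect and in 0 of 20 sets without any. In these region sets the species differed at random and independently, with a smaller spread than measured and no close relatives. These rates therefore come from a simpler setting than the data.

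The alternative settings on that list were no or plain background subtraction, quantile normalization, centring on the 75th percentile or on the Salvia control spots, no scaling, mean in place of median pixels or spots, detected fragments only, replicate number as a block, array weights, a trended robust prior, session or slide as a random block, fits of only the genotypes compared, other size minimums, other distances and groupings, and leaving out each array, species or region. Alternatives chosen after seeing the data were leaving out marked spots, session 5, S. fruticosa, the second scan period, fragment N17 or fragments not detected on every array, and changing the signal level of the arrays. Files were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, analysed in R 4.3.3 with limma 3.58.1, and plotted with matplotlib 3.10.9.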

Results

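Genomic DNA from leaves of 15 *Salvia* (sage) genotypes was hybridised to an array of 285 anonymous DNA fragments, each printed as 4 spots, that had been enriched for sequences of the genus by subtraction. The genotypes were S. officinalis (common sage) with its grey and purple varieties, S. lavandulifolia, S. sclarea (clary sage), S. elegans (pineapple sage), S. microphylla, S. mexicana, S. fruticosa (Greek sage), S. lyrata, S. runcinata, S. lanceolata, S. przewalskii, S. sinica and S. miltiorrhiza (danshen), or 13 species when the S. officinalis genotypes were averaged. Per the labels every genotype had 2 biological replicates. S. miltiorrhiza was represented by 1 array, because every spot of its replicate 1 array read 0, which left 29 arrays. Fragments are named by their position identifiers, since the files do not pair them with genes or sequences. All differences below are in log2 units of background-corrected signal centred on each array's median, and the number of arrays limits their precision.

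The arrays differed widely in brightness. The median net signal per array was 23 and 30 scanner units for S. fruticosa, 4147 and 1330 for S. sinica, and between 89 and 740 for the other genotypes. The median genotype had 249 of the 285 fragments detected on every one of its arrays. S. fruticosa had 131 and S. mexicana 210, while S. sinica and S. miltiorrhiza each had 278. No fragment was missing from every genotype, and 127 were detected on every array of all 15.

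**Figure D1:**
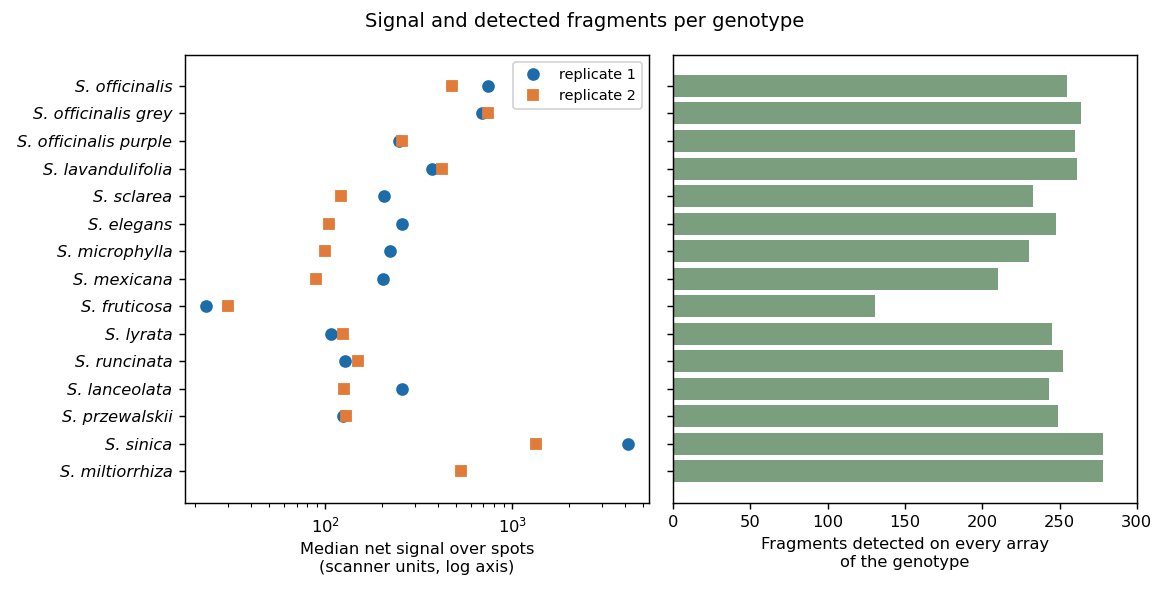
Left, the median net signal of each of the 29 arrays in scanner units on a log axis, with replicate 1 as circles and replicate 2 as squares; right, bars give the number of fragments detected on every array of the genotype. S. fruticosa is dimmest, at 23 and 30 units with 131 detected fragments, and S. sinica is brightest, at 4147 and 1330 units with 278.

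Replicate arrays of a genotype resembled each other closely. Over the 285 fragments their Pearson correlation averaged 0.974 ± 0.0183 (SD, n = 14 pairs), from 0.934 in S. elegans to 0.995 in S. runcinata. Arrays of different genotypes averaged 0.744, a difference of 0.230 (two-sided permutation test, p = 1e-05, the smallest that 100000 permutations can give). Of the 28 arrays with a replicate, 25 had that replicate as their nearest array. Both arrays of the purple variety instead lay nearest to S. lavandulifolia replicate 1 (r = 0.976 and 0.970, against 0.946 with each other). The log2 difference between the 2 purple arrays had an SD of 0.453 over fragments, the largest of the 14 pairs. S. mexicana replicate 2 lay nearest to S. microphylla replicate 2 (r = 0.976, against 0.960 with its own replicate). The latter 2 arrays were both of session 12, while S. mexicana replicate 1 was of session 7, so their likeness is mixed with session. The replicate pairs of S. officinalis (r = 0.994) and S. runcinata shared a slide, which the other pairs did not.

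Nearly all fragments differed in signal between genotypes. In limma's moderated F test over the 15 genotypes 282 of 285 fragments had an adjusted p under 0.05, and for 248 of them the highest and lowest genotypes were at least 2-fold apart. The median range between genotypes was 1.78 log2 units. The largest F belonged to B11, which ranged from 3.08 in the purple variety to -0.59 in S. lanceolata, and to O17, which ranged from 2.47 in S. officinalis to -3.26 in S. sinica. A8 and L4 had the smallest spread between genotypes, with SDs of 0.14 and 0.16. The count cannot be read as that many true differences: on simulated arrays with the measured brightness, the same test called 50.3% of unchanged fragments, against 2.04% once all arrays had been brought to 1 median signal.

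Pairs of genotypes ranged from hardly separable to strongly different. Over the 105 pairs the number of differing fragments ran from 0 to 199, with a median of 147. The purple variety and S. lavandulifolia differed in 0 fragments (limma, with 25 at an unadjusted p under 0.05 and a smallest adjusted p of 0.470), and the correlation of their means was 0.983. S. microphylla and S. mexicana differed in 2 and S. lyrata and S. runcinata in 5. Some of these arrays shared a session: replicate 2 of S. microphylla and of S. mexicana (session 12), and S. lyrata replicate 1 with both S. runcinata arrays (session 8). Average-linkage clustering placed the purple variety with S. lavandulifolia and S. officinalis with the grey variety, and then joined these 4 genotypes, each in 100% of 1000 resamples of the fragments. S. mexicana with S. microphylla, and S. przewalskii with S. sinica and S. miltiorrhiza, also formed groups in 100%. S. lanceolata with S. lyrata appeared in only 59.5%, and the joining of S. runcinata to them in 92.4%.

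**Figure D2:**
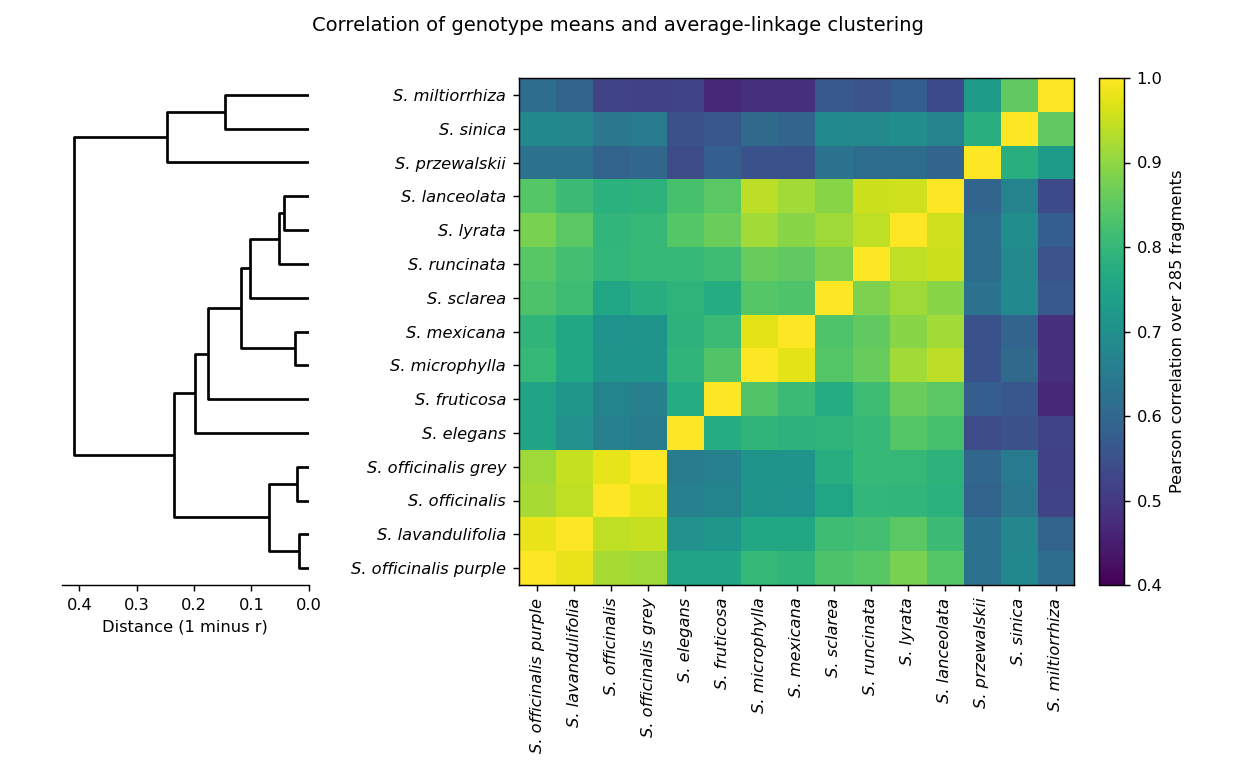
Average-linkage tree of the 15 genotypes (horizontal axis, 1 minus Pearson correlation) beside a heat map of the correlation between genotype means over 285 fragments. The 3 Asian species form 1 branch, and the purple variety joins S. lavandulifolia (r = 0.983) before S. officinalis and the grey variety.

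The first question was whether close relatives of S. officinalis could be told apart. S. officinalis and its grey variety differed in 10 fragments, 9 of them higher in S. officinalis. Both S. officinalis arrays shared 1 slide, 1 hybridisation session and a photomultiplier setting of 55. The arrays of the grey and purple varieties came from other slides and sessions at a setting of 50. Differences of S. officinalis from either variety are therefore mixed with those of slide, session and setting. B11 stood 3.63-fold higher in S. officinalis (3.07 ± 0.05 against 1.21 ± 0.18, SD, n = 2 arrays each; difference 1.86, SE 0.18, adjusted p = 4.41e-07 in limma), followed by A11 (2.39-fold; 1.26, SE 0.23, adjusted p = 0.00268), which did not pass with quantile normalization (0.99, adjusted p = 0.0725). K3 was the 1 fragment higher in the grey variety (-0.71, SE 0.15, adjusted p = 0.0109). The count was 4 with no background correction, 1 with plain subtraction, 4 with session and 2 with slide as a random block, 1 without S. officinalis replicate 2 or without grey replicate 2, and 5 after net signals had been brought to 1 median, an alternative added after the data were seen; all 5 were among the 10 and K3 was not among them (adjusted p = 0.0573). The split of 9 higher and 1 lower became 2 and 2 with quantile normalization, 2 and 4 with centring on the 75th percentile, and 1 and 3 with centring on the Salvia control spots, which moved the median difference of all fragments by -0.10, -0.20 and -0.43; with no scaling (a shift of -0.25) the count was 0 in limma.

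S. officinalis and its purple variety differed in 105 fragments, 55 higher in S. officinalis and 50 higher in the purple variety. E7 was 8.70-fold higher in S. officinalis (3.10 ± 0.23 against -0.02 ± 0.15, n = 2 each; difference 3.12, SE 0.16, adjusted p = 1.31e-12 in limma) and N13 7.86-fold higher (2.97, SE 0.28, adjusted p = 6.42e-08). E14 and G14 were the largest in the other direction (-1.29, SE 0.35, and -1.17, SE 0.27), with SDs of 0.88 and 0.60 over the 2 purple arrays. With net signals brought to 1 median the count was 57 (46 higher in S. officinalis and 11 lower), of which 55 were among the 105, and neither E14 (adjusted p = 0.108) nor G14 (adjusted p = 0.238) passed. The count was 48 without S. officinalis replicate 1, 56 without S. officinalis replicate 2, 67 without purple replicate 1, 41 with slide as a random block, 40 with no background correction, 37 with plain subtraction and 43 among the 127 fragments detected on every array. Higher and lower fragments numbered 19 and 152 with centring on the 75th percentile, 12 and 101 on the Salvia control spots and 111 and 0 with no scaling, with shifts of the median difference of -0.47, -0.49 and 1.04.

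The grey and purple varieties differed in 79 fragments, 29 higher in the grey variety and 50 higher in the purple. The same fragments N13 (2.79, SE 0.28) and E7 (2.51, SE 0.16) led among those higher in the grey variety, by 6.91-fold and 5.69-fold. E14 (-1.95, SE 0.35, adjusted p = 0.000286 in limma) and A11 (-1.92, SE 0.23, adjusted p = 1.62e-06 in limma) were higher in the purple variety. The 2 purple arrays lay far apart for E14 (SD 0.88) but not for A11 (SD 0.01). With signals at 1 median 28 fragments remained, all among the 79, with 20 higher in the grey variety and 8 higher in the purple. Without grey replicate 1 the count was 48, with no background correction 29, with plain subtraction 22 and among the fragments detected on every array 18. The split was 26 and 20 with quantile normalization, 18 and 90 with centring on the 75th percentile (shift -0.27), and 193 and 0 with no scaling (shift 1.29).

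S. lavandulifolia, with S. officinalis taken as the mean of its 3 genotypes, differed from it in 19 fragments, 18 of them higher in S. officinalis. Taken singly, S. officinalis itself differed from S. lavandulifolia in 34 fragments, 15 of them over 2-fold, the grey variety in 24 and the purple variety in 0. Only A19 and M15 had all 6 S. officinalis arrays apart from both S. lavandulifolia arrays. A19 was 1.85-fold higher in S. officinalis (0.89, SE 0.16, adjusted p = 0.000601 in limma) and M15 lower (-0.47, SE 0.13, adjusted p = 0.0216 in limma). At 1 median 16 fragments differed, all among the 19. The count was 9 without S. lavandulifolia replicate 1, 12 without replicate 2, 11 with plain subtraction and 9 among the fragments detected on every array, and the split was 11 and 2 with quantile normalization and 8 and 5 with centring on the 75th percentile (shift -0.22, and 0.25 with no scaling, where the split was 4 and 0).

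S. fruticosa was further from S. officinalis, with 180 differing fragments, 59 higher in S. officinalis and 121 higher in S. fruticosa. B11 and K7 were detected on all 6 S. officinalis arrays and on neither S. fruticosa array, and were at least 6.20-fold and at least 5.88-fold higher in S. officinalis (differences 2.73, SE 0.15, and 2.64, SE 0.16). Here at least means that the level of S. fruticosa was set at the lowest signal among the detected fragments of its arrays, or at the fragment's own signal where that was higher. The bounds concern the mean of the 3 S. officinalis genotypes. For B11 the grey variety stood at only 1.21, against 3.07 in S. officinalis itself and -0.27 in S. fruticosa, so its bound does not hold for the grey variety. I17 was detected on both S. fruticosa arrays and 2 of the 6 S. officinalis arrays (-2.92, SE 0.31, adjusted p = 6.09e-08 in limma), and H14 (-2.73, SE 0.29) was detected in neither species and has no fold. Dimness alone produces such calls: on simulated arrays of the measured brightness 71.0% of unchanged fragments were called in this comparison, against 10.8% with signals at 1 median. With signals at 1 median 196 fragments differed (61 and 135), 121 of them in the same direction as before and 4 in the opposite one. Among the 127 fragments detected on every array 62 differed. Quantile normalization gave 73 and 93, centring on the 75th percentile 31 and 184, on the Salvia control spots 18 and 168, and no scaling 259 and 0, with shifts of 0.11, -0.40, -0.48 and 2.72.

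The next question concerned the relatives of S. miltiorrhiza, whose single array was assumed to vary like those of the other genotypes. S. miltiorrhiza and S. sinica differed in 71 fragments, 57 higher in S. miltiorrhiza. L1 (3.32, SE 0.40) and N1 (3.22, SE 0.36) had the largest differences, but neither was detected in either species, so no fold is given. With quantile normalization neither passed (adjusted p = 0.850 for N1 in limma). N17, which lies beside a dye spot (-1.26, SE 0.25), and F3 (2.17-fold, -1.11, SE 0.32) were higher in S. sinica. N17 was detected on only 1 of the 2 S. sinica arrays, so no fold is given for it. With signals at 1 median 43 fragments differed, all among the 71, and without S. sinica replicate 1 the count was 37. It fell to 18 with no background correction, to 6 with plain background subtraction and to 11 among the 127 fragments detected on every array. The split of 57 and 14 became 29 and 27 with quantile normalization, 40 and 23 with centring on the 75th percentile, 14 and 10 on the Salvia control spots, and 0 and 267 with no scaling, with shifts of -0.18, -0.14, -0.42 and -2.54.

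S. miltiorrhiza and S. przewalskii differed in 84 fragments, 39 higher in S. miltiorrhiza and 45 higher in S. przewalskii. G4 was detected in S. miltiorrhiza and on neither S. przewalskii array and was at least 5.07-fold higher (2.68, SE 0.19, adjusted p = 1.56e-09 in limma), and K2 was 5.78-fold higher (2.53, SE 0.29). O11 was 10.0-fold higher in S. przewalskii (-3.33, SE 0.30, adjusted p = 2.81e-08 in limma) and F7 6.49-fold higher (-2.70, SE 0.23). At 1 median signal 119 fragments differed (71 and 48), and 74 of these were among the 84. Among the 127 fragments detected on every array 31 differed. The split was 77 and 2 with no scaling (shift 1.18).

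A further question was which fragments mark a single species. A fragment counted as specific when its adjusted p was under 0.05 against the mean of the other 12 species, its difference was at least 1 log2 unit and every array of the species lay above every array of all others. By this rule 95 fragments were specific: 25 to S. miltiorrhiza, 22 to S. przewalskii, 21 to S. fruticosa, 9 to S. sclarea, 7 to S. elegans, 4 to S. mexicana, 3 to S. runcinata, 2 to S. microphylla and 1 each to S. lyrata and S. sinica. S. officinalis, S. lavandulifolia and S. lanceolata had 0, although limma placed 73, 38 and 69 fragments higher in them at an unadjusted p under 0.05. Of these species' fragments, 15, 13 and 3 passed the adjusted p and size minimum and failed only because arrays overlapped. That condition is harder to meet with the 6 arrays of S. officinalis than with the 1 of S. miltiorrhiza, so the counts are not strictly comparable. The labels also do not give which genotypes were outside the pool used for the subtraction. Any effect of that pool on these counts or on the distances between species was not tested. With 15 genotypes taken singly, S. officinalis had 9, the grey variety 2 and the purple variety 0.

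The S. elegans fragments showed the largest differences. B2 (4.46, SE 0.24, adjusted p = 1.52e-12 in limma) and D2 (4.19, SE 0.21) were higher in S. elegans than the mean of the other species. Each was detected on both S. elegans arrays and on 4 of the 27 arrays of other species, so no fold is given. In S. przewalskii, O11 was higher by 3.35 (SE 0.18), with detection on 17 of the 27 arrays of other species, and F7 was 5.65-fold (2.50, SE 0.14). G6 and F10 were 8.85-fold and 8.32-fold higher in S. sclarea (3.15, SE 0.12, and 3.06, SE 0.14). N7 (2.85, SE 0.12) and F14 (1.94, SE 0.18) stood out in S. mexicana, A16 (2.43, SE 0.18) and J15 (2.21, SE 0.19) in S. runcinata, G2 (1.32, SE 0.18) and C3 (1.19, SE 0.18) in S. microphylla, and D11 (1.07, SE 0.18) in S. lyrata. The nearest species was S. microphylla for N7 and F14 and S. lanceolata for A16 and J15. In S. miltiorrhiza, A11 was 5.19-fold higher (2.38, SE 0.23), whereas H17 (3.10, SE 0.27) lay above the nearest S. sinica array by only 0.01, and P6 of S. sinica lay above S. miltiorrhiza by less than that.

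**Figure D3:**
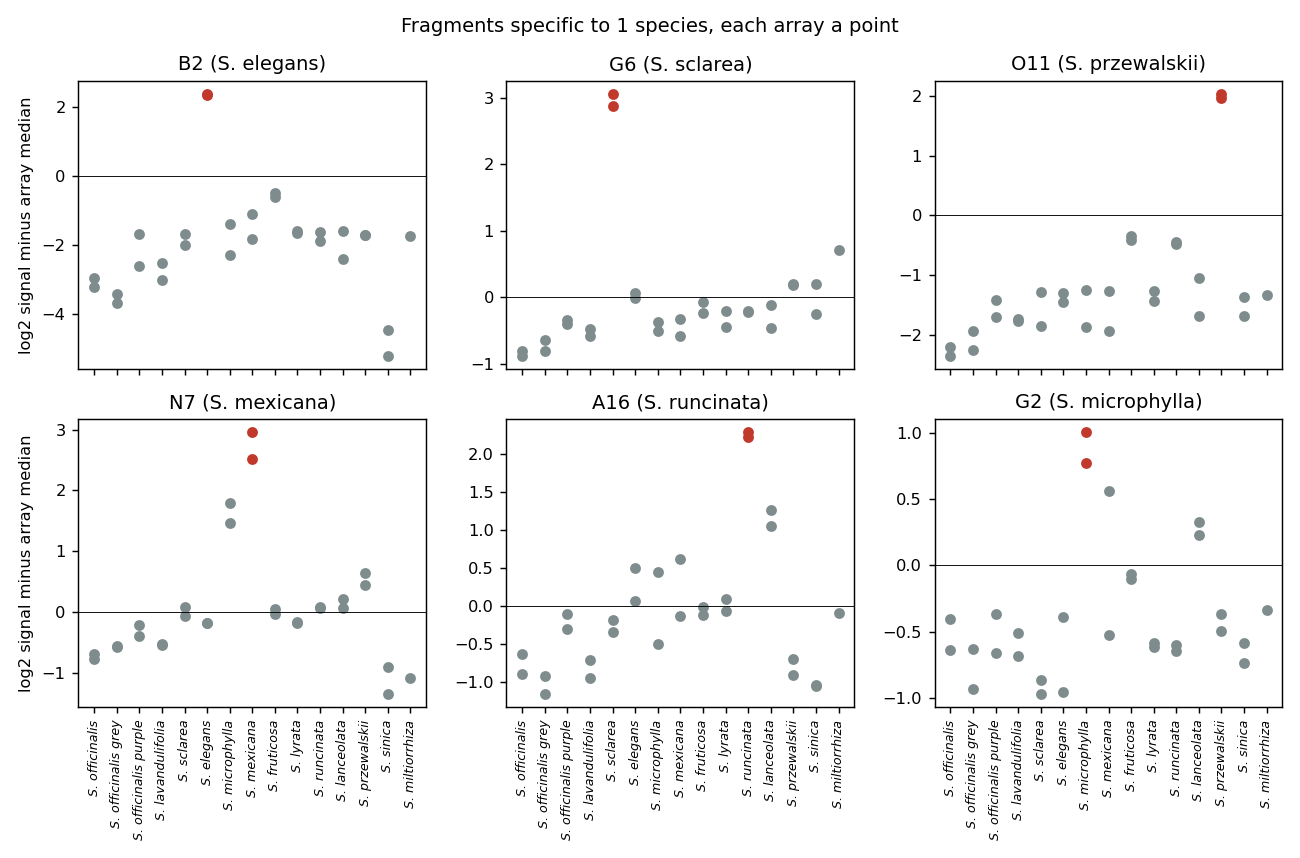
Log2 signal minus the array median (vertical axis) of 6 fragments in 15 genotypes (horizontal axis), with each array a point and the arrays of the species to which the fragment is specific in red. The S. elegans arrays lie at 2.36 on average for B2 and all arrays of other species below the array median.

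Most of these sets stayed in place when all arrays were brought to 1 median signal. The 9 fragments of S. sclarea and the 22 of S. przewalskii were specific again, as were 22 of the 25 of S. miltiorrhiza, 6 of the 7 of S. elegans, all 4 of S. mexicana and all 3 of S. runcinata. Of the 21 of S. fruticosa only 4 were. In all, 19 fragments were specific to S. fruticosa at 1 median, and all 19 were detected on both of its arrays. Its largest with signals as scanned, I1 (1.72, SE 0.23) and G1 (1.66, SE 0.22), were not detected on either of its arrays. At 1 median their differences shrank to 0.63 (adjusted p = 1.76e-05 in limma) and 0.49 (adjusted p = 0.00167 in limma), under the minimum of 1 log2 unit. H17, C3 and P6 were not specific either at 1 median. In the mirror count 30 fragments lay below all other species in S. sinica, 15 in S. miltiorrhiza and 6 in S. przewalskii; at 1 median 1 of these 30, 14 of the 15 and 5 of the 6 were low again. A 4-fold change in S. elegans was recovered as specific in 81.8% of simulated cases and an 8-fold change in 92.3%. All other species had equal true levels in that simulation. Recovery among species that differ from each other, as here, was not tested.

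**Figure D4:**
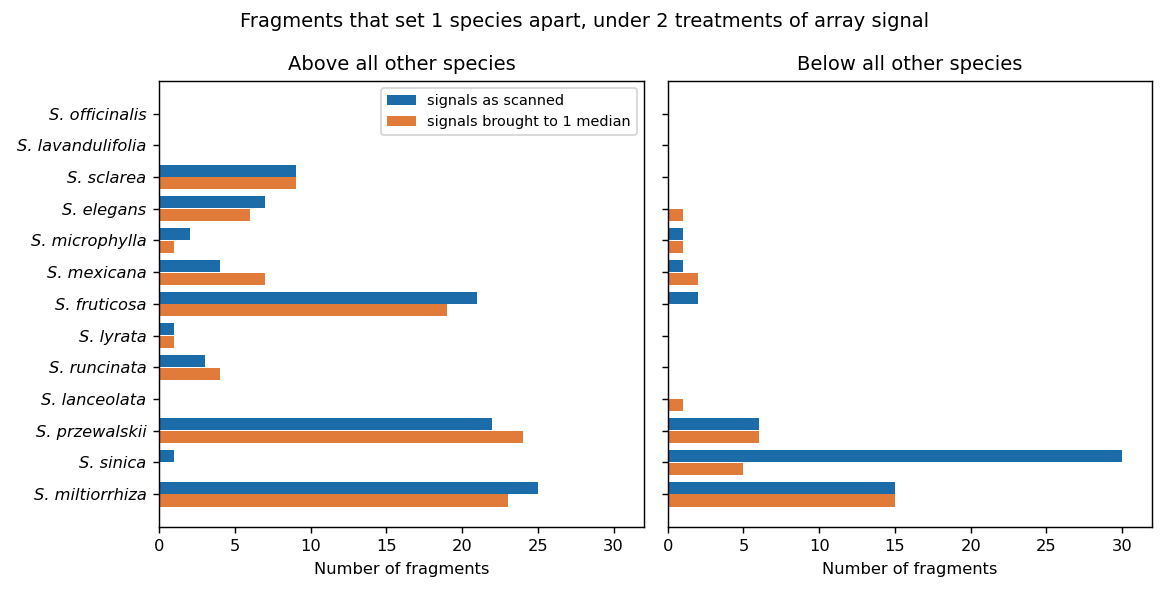
Number of fragments (horizontal axis) that lie above (left) or below (right) all other species in each of 13 species, with signals as scanned in blue and brought to 1 median in orange. The count of low fragments in S. sinica is 30 with signals as scanned and 5 at 1 median, while S. przewalskii has 22 and 24 high fragments.

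The last question was whether species group by geographical origin, here the native range known for each species, since the labels do not give where the leaves came from. Species of the same region were closer (mean distance 0.169) than species of different regions (0.287), a difference of 0.119 (two-sided permutation test over 13 species, p = 0.00109). The 3 Asian species stood apart, at mean distances of 0.398 from Europe, 0.436 from America and 0.392 from Africa. The remaining regions were close to each other, at 0.202 between Europe and America, 0.161 between Europe and Africa and 0.114 between America and Africa. For 9 of the 13 species the nearest species was of the same region. S. sclarea, S. fruticosa and S. lanceolata were nearest to the American S. lyrata, and S. lyrata to S. lanceolata. Replicate 2 of S. sclarea and of S. lyrata shared a slide and session 9, so their likeness is mixed with both. The S. fruticosa arrays were the dimmest, with the smallest spread over fragments (SD 0.69), which limits the placing of this species. Without Asia the difference was 0.0116 (permutation p = 0.520), and from presence or absence calls it was -0.000297 (permutation p = 0.992). Among pairs of arrays the difference was 0.187 in the same hybridisation session, which rests on only 3 pairs within a region, and 0.0963 in different sessions. It was 0.131 in the same scan period and 0.0702 in different periods. Over species within the first period alone it was 0.137 (permutation p = 0.00415).

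Single fragments followed the same division. Asia differed from the other regions in 120 fragments, 52 higher and 68 lower. H17 was 11.5-fold higher in the Asian species (2.49 ± 0.19 against -1.04 ± 0.36, SD, n = 3 and 10 species; difference 3.53, SE 0.20, adjusted p = 9.05e-08 in limma) and M12 4.17-fold higher (2.06, SE 0.19). C2 (-1.66, SE 0.33) and F1 (-1.62, SE 0.42) had the largest differences in the other direction. Bringing signals to 1 median, 133 fragments differed, including 110 of the 120. The split was 46 and 31 with centring on the Salvia control spots and 69 and 0 with no scaling, with shifts of 0.16 and 1.36.

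Africa differed in 4 fragments. A16 (2.03, SE 0.31), A14 (1.95, SE 0.19) and J15 (1.65, SE 0.28) were higher in S. runcinata and S. lanceolata, and H17 was lower (-1.34, SE 0.23), being high in the Asian species. The count was 1 without S. runcinata, 7 without S. microphylla replicate 1, and 1 (higher) with centring on the Salvia control spots and 0 with no scaling, where the median difference shifted by -0.26 and -0.46. America differed in 1 fragment, again H17 (-1.42, SE 0.18, adjusted p = 0.00102 in limma), and the count was 4 without S. elegans replicate 1, 12 without S. elegans, and 2 without S. sinica or its replicate 1. H17 in Africa and America, and J15 here, were chosen for naming after their values were seen. Europe differed in 0 fragments in limma, with 31 at an unadjusted p under 0.05; the count was 12 without S. sclarea, 23 without S. fruticosa, and 14, all higher in Europe, with centring on the Salvia control spots (shift 0.37).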

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

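The tests of S. fruticosa's and S. sinica's fragments, the choice of S. miltiorrhiza's fragments without session 5, the tests of the session of the purple arrays and of a wrong plant name, and the 50% level used below for control spots were chosen after the results were seen; the test of session 5 for S. miltiorrhiza, that of unequal signal for the purple arrays and the regroupings of species were written down before their results.

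S. elegans stood out among the 4 American species, because its mean distance to the other American species was 0.192, against 0.116 for the next, a gap of 0.870 of the whole range which is above the critical value for 4 values. Of 8 such groups checked this was the only one past its critical value. Chance gives about 1 in 20 for each group, so 1 of 8 can easily arise by chance. The 4 mean distances also share pairwise distances and are not independent, as the critical value assumes.

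Control spots for Rubisco, for the sequence named a/b and for the cloning vector, which no comparison used, gave signal on some arrays. Of 116 values of 4 controls (HPPR the fourth), 86 exceeded the DMSO blank spots of their array by 2 SDs, and 9 of these exceeded 50% of the array's median fragment signal. For a/b the net signals were 462.5 on S. elegans replicate 1, 274 on S. miltiorrhiza replicate 2, 239.25 on purple replicate 1 and 17 on S. fruticosa replicate 2. For Rubisco they were 513.25, 384.25, 360 and 26 on the same arrays in that order, and for the vector 172.75 on S. elegans replicate 1. The first 3 of these arrays are the 3 arrays of hybridisation session 5, and S. fruticosa replicate 2 is an array with a median net signal of 30. The differences of the session 5 array from its replicate correlated across fragments between the purple variety and S. elegans (r = 0.463; fragments are not independent replicates).

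The first pattern weighed is the set of fragments that mark the dimmest and the brightest species. Of the 21 fragments specific to S. fruticosa, 17 were not detected on both of its arrays, and once all arrays had been dimmed to the signal of S. fruticosa 0 of these 17 stayed apart, with their median difference falling from 1.42 to 0.06; an offset that raises dim arrays is a candidate explanation. The other 4 (C2, F1, J17 and K17) were detected on both arrays, and 4 of 4 stayed apart, which argues against the offset for them. Of the 30 fragments low in S. sinica, 6 stayed apart after dimming and at 1 median signal only 1 was low again, so a bright array least raised by the offset may account for this set, although dimming also shrinks true differences. Whether S. fruticosa and S. sinica also differ in these fragments as species remains open and untested.

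The second pattern is that S. miltiorrhiza has 25 specific fragments while only 1 of its arrays was used. A signal shared by the arrays of session 5 would raise these fragments on the session's other arrays too, but the larger of the median differences between a session 5 array and its replicate over these fragments was 0.113 in S. elegans (SD 0.44 over fragments, 16 of 25 higher) and the other was 0.06 in the purple variety (SD 0.41, 18 of 25 higher), against a median difference of 1.67 that marks S. miltiorrhiza. Asking fragments to lie above only the arrays outside session 5 gave the same 25. No fragment was thus kept out by that condition for lying lower than on the other session 5 arrays. The adjusted p and size minimum still came from all arrays, so they could leave out fragments also raised on those arrays. The small median differences argue against a shared session signal as the source of the whole set. A smaller contribution stays open, given the correlation of 0.463 above. A property of that single array or plant, and a difference of the species, both remain open without a second array.

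The third pattern is the purple variety, whose nearest genotype was S. lavandulifolia and not S. officinalis. The 2 purple arrays were less alike with each other (r = 0.946) than either was with S. lavandulifolia replicate 1, and purple replicate 1 is a session 5 array. The nearest array of another genotype shared the session for 0 of the 2 purple arrays, and S. lavandulifolia stayed nearest for 2 of 2 after all arrays had been dimmed alike, which argues against arrays hybridised in the same session and against unequal signal of the arrays. For plant material under a wrong name, 0 of 2 purple arrays lay nearest to S. officinalis or the grey variety, which keeps it open, since such material on both arrays and a true likeness of the variety to S. lavandulifolia would look alike. That the purple variety may carry S. lavandulifolia-like DNA is thus a hypothesis only.

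Other groupings of the 13 species into sets of the sizes of the regions, 100 in all with the real one included, were compared with the real regions. For Asia 1 of 100, the real one itself, gave 120 fragments, which is the smallest share that 100 groupings can give. The highest other count, 119, came from the single other drawn grouping that also kept the 3 Asian species together. Groupings with 2 of them gave at most 20. Such a count was thus rare among random groupings. The test cannot tell native region from any other source of likeness among these 3 species. For America 6 of 100 gave at least the real 1, with 62 as the highest other, so chance cannot be excluded. For Europe the real count was 0, which every grouping must reach, so the comparison could not decide the question. The highest other count for Europe was 6. The 62, many times the real count, came from a set of 4 that held all 3 Asian species with S. officinalis, and so points to the same Asian structure of the species.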

How the results depend on the processing

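The alternatives on marked spots, session 5, S. fruticosa, the scan periods, fragments detected on every array, dimming, fragment N17 and 1 median signal were chosen after the data were seen; the others were planned. Replicate agreement and the median number of detected fragments kept their direction and stayed close to the reported values under all alternatives run for them, and the F test count did so except where fewer fragments were tested. The grouping by region kept its direction and its p under 0.05 except without Asia (0.0116) and from presence or absence calls (-0.000297). Where no cause is named below, the cause was not tested. Signal over background limits S. fruticosa most, and leaving out undetected fragments in the planned way removed none, so that alternative shows nothing.

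In what follows the pairs are S. officinalis with grey (reported 10), with purple (105), grey with purple (79), S. officinalis with S. lavandulifolia (19) and with S. fruticosa (180), S. miltiorrhiza with S. sinica (71) and with S. przewalskii (84); the regions are Europe (0), America (1), Asia (120) and Africa (4). Only counts that moved by over 1.5 times are given. No background correction gave 4 for S. officinalis with grey, 40 with purple, 29 for grey with purple, 18 for S. miltiorrhiza with S. sinica and 0 for America. Plain subtraction gave 1, 37 and 22 for the S. officinalis varieties in the same order, 11 for S. lavandulifolia and 6 for S. sinica. Quantile normalization gave 4, 47 and 46 for the varieties, 2 for Europe, 2 for America and 8 for Africa. Centring on the 75th percentile gave 6 for grey and 171 for purple. Centring on the Salvia control spots gave 4 for grey, 44 for grey with purple, 4 for S. lavandulifolia, 24 for S. sinica, 36 for S. przewalskii, 14 for Europe, 77 for Asia and 1 for Africa. No scaling gave 0 for grey, 193 for grey with purple, 4 for S. lavandulifolia, 267 for S. sinica, 189 specific fragments (reported 95), 0 for America, 69 for Asia and 0 for Africa, and turned the S. fruticosa-specific differences of I1 to -0.18 and of G1 to -0.24. Mean pixels gave 4 and array weights 23 for grey. Fits of only the genotypes compared, which have fewer arrays, gave 57 for purple, 10 for S. lavandulifolia, 33 for S. sinica and 145 for S. przewalskii. With 15 genotypes Europe had 22 and Africa 7. A minimum difference of 2 log2 units gave 24 specific fragments and no minimum 147.

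Session as a random block (estimated correlation 0.418) gave 4 for grey, and slide as a random block (0.740) gave 2 for grey and 41 for purple. The replicate numbers were checked for pairing: over 91 pairs of genotypes the deviations of same-numbered arrays correlated at 0.0376 on average, from -0.575 to 0.786. In 4 genotypes the number marks shared hybridisation sessions. Of their 6 pairs, 2 also shared both slides, S. microphylla with S. lanceolata (0.786) and S. fruticosa with S. przewalskii (0.251), so for these the number marks a shared slide; the other 4 pairs ran from -0.379 to 0.303. Neither slide-sharing pair is among the pairs listed above, and over all genotypes the number was not taken as a pairing. With the replicate number as a block the counts were 282 for the F test, 13, 109 and 80 for the varieties, 21 for S. lavandulifolia, 180 for S. fruticosa, 65 for S. sinica, 88 for S. przewalskii and 95 specific fragments, and no count moved by over 1.5 times.

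Leaving out marked spots, which removes many dim values, gave 103 for the F test, 65 for purple, 48 for S. fruticosa, 12 specific fragments, 1 for Europe, 10 for America, 68 for Asia and 0 for Africa. Only fragments detected on every array, 127 in all, gave 124 for the F test, 43 for purple, 18 for grey with purple, 9 for S. lavandulifolia, 62 for S. fruticosa, 11 for S. sinica, 31 for S. przewalskii, 22 specific fragments, 12 for America and 2 for Africa. Without the S. fruticosa arrays Europe had 23. All arrays dimmed to S. fruticosa gave 50 for purple, 27 for grey with purple, 40 for S. sinica, 35 specific fragments, 2 for Europe and 2 for America. Net signals at 1 median gave 5 for grey, 57 for purple, 28 for grey with purple and 43 for S. sinica.

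Leaving out 1 array or 1 species at a time, with a lone array assumed to vary like the others, the counts ran from 277 to 284 for the F test, 1 to 12 for grey, 48 to 81 for purple, 48 to 78 for grey with purple, 9 to 22 for S. lavandulifolia, 146 to 184 for S. fruticosa, 37 to 84 for S. sinica, 60 to 66 for S. przewalskii, 93 to 113 for specific fragments, 0 to 23 for Europe, 1 to 12 for America, 81 to 137 for Asia and 1 to 7 for Africa. The region difference ran from 0.0899 to 0.144 and the replicate difference from 0.219 to 0.237.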

Other observations

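The tests and counts in this part were chosen after the data were seen.

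Several pairs of species shared fragments that set them above all other species. By the rule used for single species applied to the 78 pairs of the 13 species, 65 fragments were private to 12 pairs, and 6 of the 12 pairs were of 1 native region, against 16 of all 78. S. sinica and S. miltiorrhiza shared 16 such fragments, S. microphylla and S. mexicana 12, S. officinalis and S. lavandulifolia 9, and S. przewalskii and S. miltiorrhiza 8. The same fragments passed with signals at 1 median for 12, 9, 7 and 6 of these. S. elegans and S. fruticosa shared 8 by this rule, of which 2 passed at 1 median. The rule does not ask for like levels in both species. B2, the largest of these 8, stood at 2.36 in S. elegans but at -0.56 in S. fruticosa, and was detected on 2 of their 4 arrays. Fragments counted above as specific to 1 species, such as B2, D2, N7, O11 and A16, are therefore counted again here. Among the clearest, O17 was higher in S. officinalis and S. lavandulifolia than in the other species (3.74, SE 0.11), where it was detected on 10 of 21 arrays, and K7 was 7.26-fold higher (2.86, SE 0.09; 19 of 21). E3 was higher in S. microphylla and S. mexicana (3.38, SE 0.13) and was detected on 9 of the 25 arrays of other species, and N7 was 5.47-fold higher (2.45, SE 0.09; 24 of 25). Because O17 and E3 were above background on fewer than 50% of the other arrays, no fold is given for them. M12 was 3.90-fold higher in S. przewalskii and S. miltiorrhiza than in the mean of the other species (1.96, SE 0.11), and A14 3.83-fold higher in S. runcinata and S. lanceolata (1.94, SE 0.11). For M12 the next species, S. sinica, stood at 1.18, close to 1.44 in S. przewalskii and 1.54 in S. miltiorrhiza.

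Within the relatives of S. officinalis the purple variety and S. lavandulifolia departed together from S. officinalis and its grey variety, with 48 fragments lower and 54 higher in limma. With signals at 1 median 38 were lower and 11 higher, of which 35 and 11 were among these. The split was 29 and 31 with quantile normalization, 22 and 177 with centring on the 75th percentile, 21 and 59 on the Salvia control spots, and 194 and 0 with no scaling. Among the lower fragments, E7 was lower by similar amounts in the purple variety (-2.81) and in S. lavandulifolia (-2.53), as were N13 (-2.88 and -3.16), C19 (-2.47 and -2.62) and J14 (-2.14 and -1.99). Among the higher ones, the 3 with the smallest adjusted p, B11, A11 and C11, owed much or all of the difference to a low level in the grey variety. B11 was at 1.21 there, against 3.07 in S. officinalis, 3.08 in the purple variety and 2.94 in S. lavandulifolia. For A11 these levels were -1.34, -0.08, 0.58 and 0.13 in the same order, and for C11 0.18, 0.98, 1.79 and 1.31. Array correlations averaged 0.965 between the purple variety and S. lavandulifolia, 0.908 between the purple variety and S. officinalis, and 0.973 between S. officinalis and the grey variety. With signals at 1 median the purple variety and S. lavandulifolia again differed in 0 fragments in limma, with 10 at an unadjusted p under 0.05.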
